A study of Aedes aegypti with 20 samples.

How the data were processed

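RNA sequencing of pedicels and heads from male and female Aedes aegypti (Liverpool strain) gave 20 libraries in 4 groups of 5. RNA was extracted with phenol and chloroform, per the labels' protocols, and a sequencing centre built the libraries. FastQC, HISAT2 and featureCounts are named in the submitters' processing notes, and their versions, the genome build and the annotation are not given in the sources used here. The deposited table holds estimated counts per transcript, not scaled between libraries, with 1 column per library. Between 54.9% and 61.9% of the values of a library, zeros included, and 35.4% to 40.8% of those above 0 were whole numbers, and the rest carried fractions. Which tool gave these fractions is not given in the sources used here. The table's column names, which call the pedicel by its hearing organ and the head by the brain, were matched to libraries through the sample descriptions, and the groups follow the labels (pedicel and head).

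Estimated counts were summed over the transcripts of a gene ID and rounded to whole numbers. Summed estimated counts per library ran from 5060010 to 9404311, which sets the precision of low values: folds of genes named with 1 to 3 counts over a group are given with counting intervals and those of genes with none with a floor of 3 counts over the group, and these cover counting error only. Genes with more counts, some with as few as 4, are given with fitted log2 folds. Of 19804 gene IDs, 11381 were tested after edgeR's filterByExpr by group and 8423 were left out. Library sizes were scaled with TMM, whose factors ran from 0.49 to 1.31. All 20 libraries entered 1 quasi-likelihood fit (edgeR 4.0.16, glmQLFit with robust estimates and glmQLFTest, in R 4.3.3) with a mean per group. The 5 contrasts were male against female in the pedicel and in the head, pedicel against head in males and in females, and the interaction of sex and tissue. P-values were adjusted by Benjamini-Hochberg over the 11381 genes of each contrast, and a gene was called at an adjusted p under 0.05. Standard errors of log2 folds were taken as the absolute log2 fold divided by the square root of the F statistic. CPM values are normalised by the TMM-scaled library sizes, and log2 CPM for the principal components used a prior count of 2. All libraries share 1 estimate of spread per gene, although pedicels varied more than heads.

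The rule for named genes, the gene lists, the tests and most alternatives were fixed before the data were examined. The rule took the largest positive and negative log2 folds among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries (for the interaction, the adjusted p and the CPM in any group). For genes with no name it allowed 2 rises and 2 falls per comparison. Of the 19804 IDs, 0 matched the RefSeq gene table of assembly AaegL5.0 used for names, so all named genes are given by ID with no function. The 29 gene lists, which covered hearing channels, cilia, neurotransmission, odour and taste receptors, clock, sex determination and markers of other tissues, rest on names and were not analysed here, and neither was the chromosomal location of the genes.

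Transcripts were compared across gene IDs for identical values in all libraries. A set of 263 transcripts of 244 gene IDs, 158 of them tested, had the same values (to 3 decimals, with a maximum above 5) as a transcript of another gene ID, with up to 21 gene IDs in a set. Counts of such copies cannot be assigned to 1 gene ID, and of the genes named in the text AAEL011275 has 1 such transcript of its 2. The level of head transcripts in a library is the median, over 50 genes, of the CPM in percent of the mean CPM of all heads. The 50 genes had at least 50 CPM in each head, an absolute log2 fold under 0.5 between the sexes in the head, and the lowest value in any of the 10 pedicels relative to the heads. Isoform usage was tested with edgeR's diffSpliceDGE and Simes' method on 11544 transcripts of 3387 genes.

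The fits were tried on simulated data with 11381 genes, 200 of them changed. Of 4-fold changes, 93% were recovered for sex in the pedicel, 96% for sex in the head, 95% for tissue in males, 99% for tissue in females and 90% for the interaction. Of 2-fold changes, 63%, 72%, 67%, 63% and 39% were recovered, in the same order. False calls numbered 38 of 194, 4 of 172, 8 of 170, 13 of 175 and 7 of 136. The excess in the pedicel arose in a simulation with more spread in pedicels than in heads. The isoform test recovered 53 of 200 genes with swapped transcripts (26.5%), with 7 false calls.

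Alternatives tried were other scalings, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0 and limma-voom (limma 3.58.1). The other scalings were edgeR's RLE (relative log expression) factors, library totals alone, and TMM factors with totals computed without the 20 most abundant genes. Also tried were fits of only the groups compared (for the interaction, all 4 groups with voom and sample quality weights) and the replicate block. A stricter threshold of 0.01, an absolute log2 fold of at least 1 and leaving out each library were tried too. Alternatives added after seeing the data left out identical copies or libraries in doubt, split the pedicels by their share of identical copies (10% or less against above 20%), and adjusted for the level of head transcripts. Differences in single values between pedicels of the sexes were tested with exact permutation tests.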

Results

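The hearing organ of the yellow fever mosquito Aedes aegypti, Johnston's organ, lies in the pedicel, the second segment of the antenna. Transcripts were measured by RNA sequencing in pedicels and in heads of males and females of the Liverpool strain. The males were virgin and the females had taken no blood meal. Animals were kept in an incubator for 2 days and frozen at zeitgeber time 12. Each of the 4 groups (male pedicel, female pedicel, male head and female head) had 5 libraries, 20 in all. The estimated counts summed to between 5060010 and 9404311 per library. The table held 34477 transcripts of 19804 gene IDs, of which 11381 genes had enough counts to be tested. Genes are given by the ID of the table, since the files used here pair no ID with a gene name. Nothing in the labels says whether the 5 libraries of a group came from separate sets of animals, so p-values measure the spread between these libraries, whether biological or technical.

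Tissue and sex both separated the libraries. The first principal component of the log2 normalised read counts (CPM) held 44.3% of the variance and parted pedicels from heads. The second held 22.3% and parted males from females. Pedicel libraries varied more than head libraries, with a biological coefficient of variation of 0.36 in pedicels and 0.20 in heads. Spearman correlations across genes between libraries of 1 group ranged from 0.844 to 0.972 in male pedicels, 0.894 to 0.968 in female pedicels, 0.957 to 0.986 in male heads and 0.963 to 0.982 in female heads. No pair of libraries in a group agreed within sampling noise, the lowest chi-square per degree of freedom being 5.54.

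**Figure D1:**
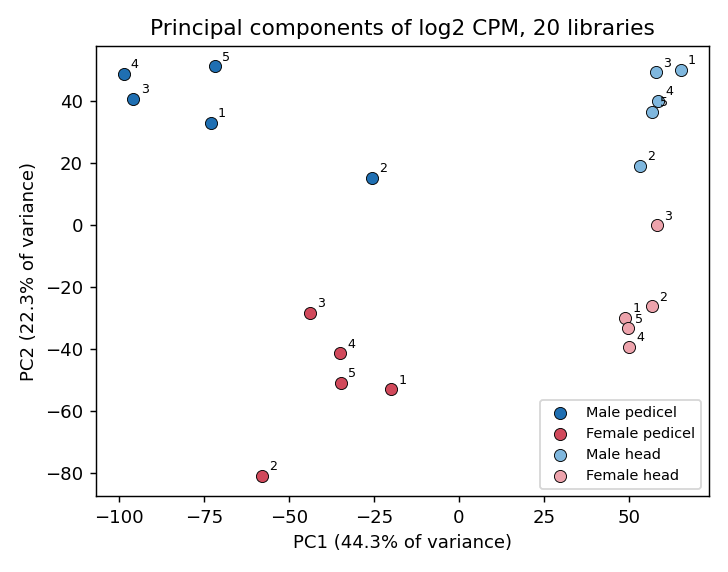
Principal components 1 and 2 (scores, no unit) of log2 CPM over 11381 genes, with 1 point per library, coloured by group and numbered by replicate. Component 1 (44.3% of the variance) separates pedicels from heads and component 2 (22.3%) separates males from females, with male pedicel 2 nearest to the heads among the male pedicels.

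The first comparison asked how the hearing organ differs between the sexes. In the pedicel, 4501 of the 11381 genes (39.5%) differed between males and females at an adjusted p under 0.05. Of them, 2093 were higher in males and 2408 higher in females. This balance turned to 2617 and 770 with library totals alone and to 2346 and 2188 with TMM without the 20 most abundant genes. It turned to 2267 and 2264 with RLE factors and to 2382 and 2364 with DESeq2. At a fold of at least 2, 605 of the 4501 were higher in males and 1138 in females, and at a fold of at least 4 the numbers were 105 and 316. AAEL008754 stood at 92.6 ± 50.6 CPM in male pedicels and 1.14 ± 0.813 CPM in female pedicels (SD, n = 5 each), a log2 fold of 6.34 (SE 0.51, edgeR adjusted p = 3.4e-08, or 7.7e-05 in a fit of the pedicel libraries alone), and all 5 male libraries lay above all 5 female libraries. AAEL020474 stood at 12 ± 2.77 CPM in male pedicels, against 3 counts over the 5 female pedicels, all of them in female pedicel 4. The observed ratio of 103 had a 95% counting interval of 35.3 to 500, which covers counting error only, and without female pedicel 4 the gene was at least 85.3-fold higher in males, with the floor set at 3 counts over the group.

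Among the genes higher in female pedicels, AAEL000732 averaged 66.5 ± 34.1 CPM in females and 0.174 ± 0.278 CPM in males (SD, n = 5 each), a log2 fold of -8.99, male over female (SE 0.65, edgeR adjusted p = 1.6e-08, or 6.9e-05 in a fit of the pedicel libraries alone). Its 4 counts in male pedicels left a log2 fold of -9.72 without male pedicel 4, where 2 counts remained (ratio 1030, 95% counting interval 285 to 8500). It was higher in females in the head too, at 61.6 ± 25.4 CPM against 1 count over the 5 male heads (ratio 2460, 95% counting interval 442 to 97300). AAEL028731 had the most negative fold among the genes that met the rule for naming, with 8390 ± 10400 CPM in female pedicels and 1.41 ± 2.56 CPM in male pedicels (log2 fold -12.60, SE 2.56, adjusted p = 1.2e-03). Its female values ranged from 46.6 to 22100 CPM between libraries, and its log2 fold was -11.85 without female pedicel 3 and -14.56 without male pedicel 3. The call on AAEL028731 was lost with limma-voom (adjusted p = 7.0e-02), and its adjusted p ran from 1.8e-06 to 2.2e-01 over all settings tried.

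**Figure D2:**
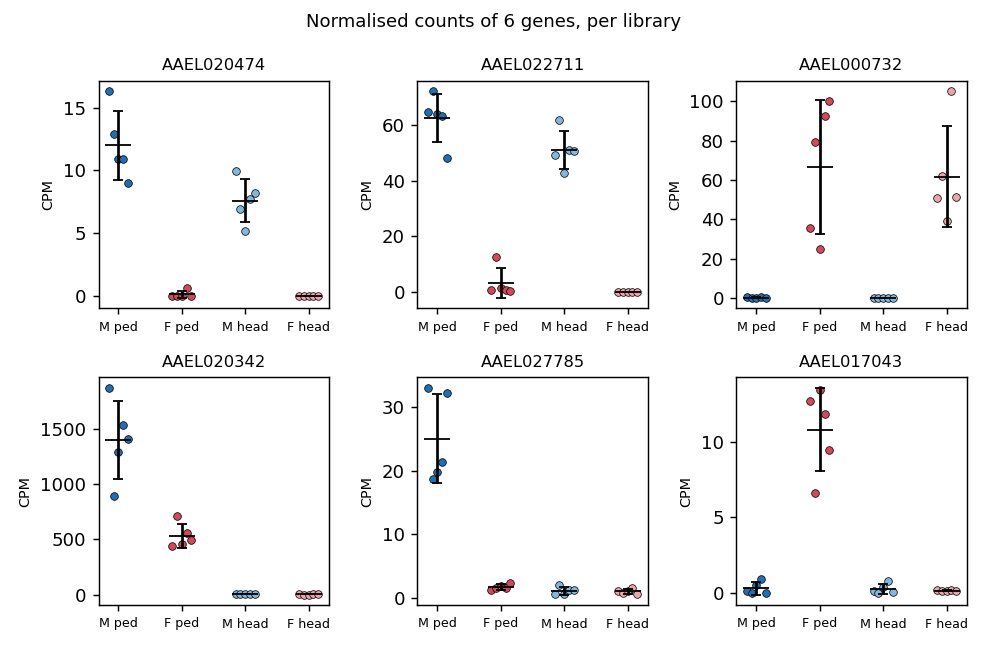
Normalised counts (CPM, linear axis) of 6 genes in each library, with the group mean as a horizontal line and the SD as an error bar (n = 5 libraries per group; M, male; F, female; ped, pedicel). AAEL020474 and AAEL022711 were higher in males in both tissues, AAEL000732 was higher in females in both tissues, AAEL020342 was higher in pedicels than in heads in both sexes, AAEL027785 was highest in male pedicels and AAEL017043 in female pedicels.

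Of 1773 genes abundant in the head, a chosen set of 50 moved with sex in the pedicel. The median level of 50 head transcripts, chosen as those with the lowest value in any pedicel library relative to the heads, was 54.6 ± 14.9% of the mean head level in female pedicels and 11.4 ± 14.1% in male pedicels (SD, n = 5 each; exact permutation p = 0.016, two-sided). Male pedicel 2 stood at 36.6%, and the other 4 male pedicels at 4.34% to 5.64%. The choice of the 50 did not use the sex of the pedicels, but it required an absolute log2 fold under 0.5 between the sexes in the head. The lowest libraries were male pedicels, though, so the choice may overstate the size of the gap between the sexes. Heads of both sexes lay between 94.5% and 108%. When this level entered the pedicel fit as a covariate, chosen after seeing the data, 150 genes differed between the sexes, 56 higher in males and 94 in females, and 142 of them were among the 4501. The log2 level correlated with sex over the 10 pedicels at a Pearson r of 0.85, so this fit cannot separate the effects of the level and of sex. The share of counts in 263 transcripts whose values were identical to those of a transcript of another gene ID also varied among pedicels, from 2.17% to 35.2%, against 2.51% to 3.72% in heads. Its mean was 13.2 ± 14.8% in male and 17.6 ± 9.01% in female pedicels (SD, n = 5 each; exact permutation p = 0.61, two-sided). With all head libraries kept in the fit, 3324 genes differed between the sexes within the 5 pedicel libraries at 10% or less. Within the 5 above 20%, 4081 genes did. In simulated data with 200 changed genes, 38 of the 194 calls in this comparison were false, and a fit of the 10 pedicel libraries alone called 3269 genes in the real data.

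**Figure D3:**
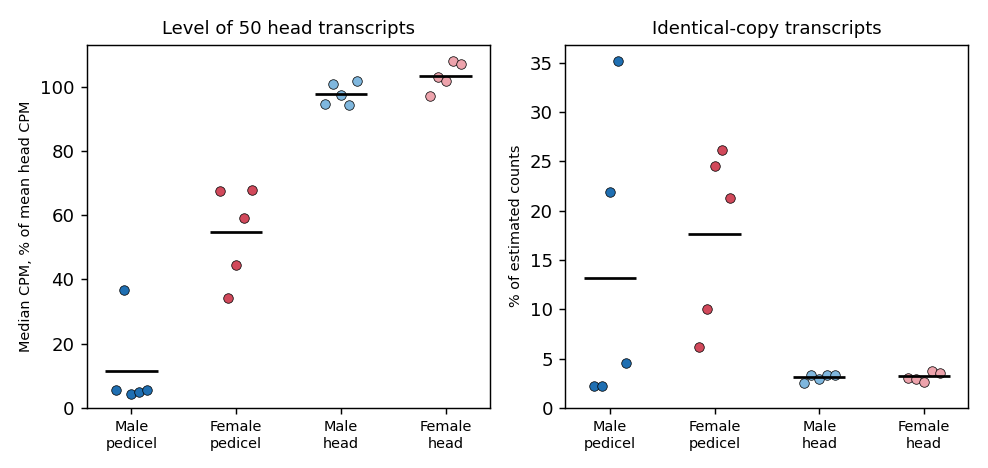
Per-library values in the 4 groups, with 1 point per library and a line at the group mean. The left panel gives the median level of 50 head transcripts in % of their mean head CPM, which lies between 34.1% and 67.8% in female pedicels and between 4.34% and 36.6% in male pedicels, and the right panel gives the % of estimated counts in identical-copy transcripts, which exceeds 20% in 2 male and 3 female pedicels.

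The head served as the second tissue in which the sexes were compared. There, 894 genes (7.86%) differed between males and females, 128 higher in males and 766 higher in females. The 128 became 334 without female head 3, 236 without male head 2, and 81 to 83 without male head 3, 4 or 5 or female head 1 or 4, and DESeq2 gave 260 higher in males and 897 in females. At a fold of at least 4, 34 genes were higher in males and 157 in females. AAEL022711 averaged 51.2 ± 6.88 CPM in male heads (SD, n = 5) and had 1 count over the 5 female heads, an observed ratio of 2120 with a 95% counting interval of 380 to 83600. The count lay in female head 3, without which the gene was at least 557-fold higher in males, with the floor set at 3 counts over the group. AAEL023202 averaged 10.8 ± 3.8 CPM in male heads and 0.519 ± 1.16 CPM in female heads (log2 fold 4.26, SE 0.88, edgeR adjusted p = 3.4e-03). All of its female head counts lay in female head 3, and without that library it was at least 111-fold higher in males, against the same floor. AAEL010235, at 208 ± 96.8 CPM in female heads, had no counts in any of the 5 male heads, which made it at least 2770-fold lower in males. AAEL000533, at 50.5 ± 22.3 CPM in female heads, had no counts in male heads either and was at least 674-fold lower. Both were higher in females in the pedicel as well, AAEL010235 at 238 ± 140 against 1.13 ± 1.67 CPM and AAEL000533 at 53.8 ± 42 against 0.351 ± 0.407 CPM.

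The number of sex differences in the head moved with the libraries used. A fit of the 10 head libraries alone called 1551 genes, 535 higher in males and 1016 in females, and a fit without male head 2 and female head 3, left out after seeing the data, called 1661, 718 higher in males and 943 in females. With library totals alone, 571 genes were called, 178 higher in males and 393 in females.

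The sex differences of the 2 tissues overlapped. Of the 894 genes called in the head, 668 (74.7%) were also called in the pedicel, where 3833 others were called, 79 higher in males in both, 569 higher in females in both and 20 in opposite directions. Independent lists of these sizes would share 23.5 male-higher, 162 female-higher and 168 opposite genes (Fisher's exact test over genes, odds ratio 5.13, p = 1.0e-109). Across the 11381 genes, the log2 folds of the pedicel and the head correlated with a Pearson r of 0.61 and a Spearman rho of 0.47. Genes are not independent replicates. The 2 comparisons share no library, but they may not be independent. Head transcripts stood at 34.1% to 67.8% of the head level in female pedicels and at 4.34% to 36.6% in male pedicels. Head RNA in female pedicels could bring sex differences of the head into the pedicel comparison, which was not tested.

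Some genes were close to limited to 1 sex in both tissues. A fold of at least 16 in the same direction in pedicel and head, with an adjusted p under 0.05 in both, was met by 5 genes higher in males, AAEL020474 and AAEL022711 among them, and by 52 genes higher in females, among them AAEL000533, AAEL000732 and AAEL010235. The median of the mean levels of the 52 genes was 41.1 CPM in female pedicels and 33.6 CPM in female heads, against 0.207 CPM in male pedicels and 0.0487 CPM in male heads. For 14 of the 52, no male head library had a count. The 16-fold limit was chosen after seeing the data.

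**Figure D4:**
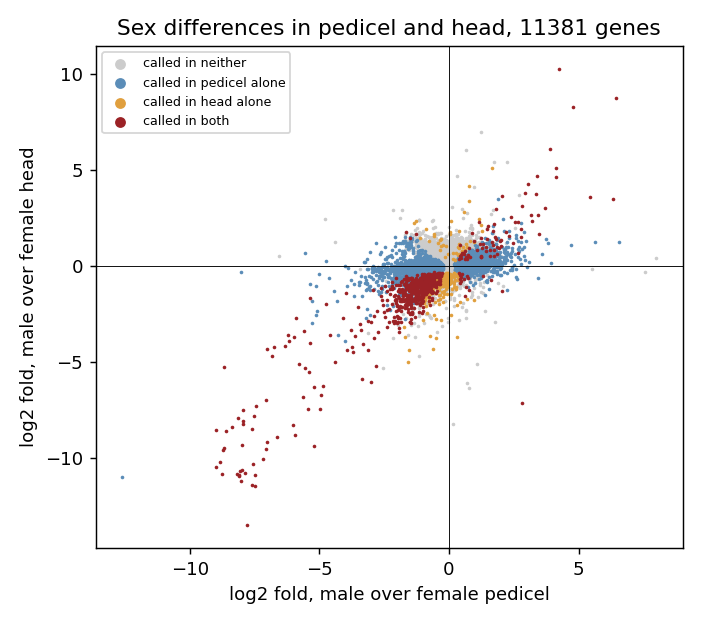
Log2 fold of male over female in the pedicel (x axis) and in the head (y axis) for 11381 genes, with 1 point per gene, coloured by whether it was called at an adjusted p under 0.05 in the pedicel, the head, both or neither. The cloud at the lower left holds the 52 genes called and at least 16-fold higher in females in both tissues, and the few points at the upper right hold the 5 such genes higher in males.

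Comparing pedicel with head in males asked which genes mark the hearing organ. In males, 5799 genes (51%) differed between the tissues, 3037 higher in the pedicel and 2762 higher in the head, a balance that turned to 1521 and 2448 with library totals alone, to 2774 and 2858 with limma-voom and to 2208 and 2217 at an adjusted p under 0.01. At a fold of at least 4, 769 were higher in the pedicel and 529 in the head. AAEL020342 stood at 1400 ± 354 CPM in male pedicels and 8.97 ± 2.17 CPM in male heads (SD, n = 5 each; log2 fold 7.28, SE 0.31, edgeR adjusted p = 8.2e-13, or 3.7e-08 in a fit of the male libraries alone), and in females it averaged 533 ± 109 CPM in pedicels against 5.15 ± 1.96 CPM in heads. AAEL019334 averaged 424 ± 771 CPM in male pedicels and 1.22 ± 2.72 CPM in male heads (log2 fold 8.72, SE 1.86, adjusted p = 6.6e-04). Male pedicel 3 alone held 1790 CPM of it, against 6.88 to 275 CPM in the other 4, and its log2 fold was 6.32 without that library. All of its male head counts lay in male head 2, without which it was at least 3680-fold higher in the pedicel, with the floor set at 3 counts over the group. The call was lost with limma-voom (adjusted p = 3.1e-01; range over all settings 6.1e-06 to 3.1e-01).

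AAEL009991 was lower in the male pedicel than in the male head, at 66.1 ± 76.3 against 877 ± 135 CPM (SD, n = 5 each; log2 fold -3.72, SE 0.54, edgeR adjusted p = 1.5e-05). Male pedicel 2, the male pedicel library with the highest level of head transcripts, held 201 CPM of it, and without that library the log2 fold was -4.75. AAEL011275 had 8 counts over the 5 male pedicels, all in male pedicel 1, and 15.4 ± 10.4 CPM in male heads (log2 fold -6.02, SE 1.31, adjusted p = 8.1e-04). Without male pedicel 1 it was at least 141-fold lower in the pedicel, with the floor set at 3 counts over the group. Its adjusted p was 5.1e-02 with limma-voom, the highest of the settings tried, and 4.6e-05 in the lowest. One of its 2 transcripts, with 245 of its 1328 estimated counts over all libraries, had the same values as a transcript of another gene ID, so these counts cannot be assigned to AAEL011275 alone.

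In females, 4028 genes (35.4%) differed between pedicel and head, 2146 higher in the pedicel and 1882 higher in the head. This balance turned to 753 and 3243 with library totals alone, to 1962 and 2099 with RLE factors and to 2101 and 2205 with DESeq2. It turned to 1864 and 2175 with TMM without the 20 most abundant genes. With the pedicels above 20% of identical-copy transcripts it was 2104 and 2261. A fold of at least 4 was reached by 575 genes higher in the pedicel and by 17 higher in the head. AAEL028790 averaged 5760 ± 3780 CPM in female pedicels and 33.9 ± 23.1 CPM in female heads (SD, n = 5 each; log2 fold 7.41, SE 1.55, edgeR adjusted p = 1.2e-03), with pedicel values from 481 to 9220 CPM. In male pedicels it ranged from 41.4 to 12700 CPM. AAEL020035 averaged 42.6 ± 84 CPM in female pedicels and 0.117 ± 0.0801 CPM in female heads (log2 fold 8.29, SE 2.18, adjusted p = 6.3e-03). Female pedicel 2 held 193 CPM of it and the other 4 libraries 1.28 to 12.1 CPM. Without female pedicel 2 its log2 fold was 5.33 and the call was lost (adjusted p = 6.7e-02), as it was with limma-voom (adjusted p = 5.0e-01; range over all settings 3.7e-07 to 5.0e-01).

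Lower in the female pedicel than in the female head were AAEL024800, at 22.9 ± 23.8 against 123 ± 14.2 CPM (SD, n = 5 each; log2 fold -2.44, SE 0.73, edgeR adjusted p = 1.5e-02), and AAEL014125, at 3.74 ± 2.01 against 14.7 ± 1.92 CPM (log2 fold -1.98, SE 0.56, adjusted p = 1.0e-02). AAEL024800 had no counts in female pedicels 2 and 3, its log2 fold was -3.05 without female pedicel 5, and its call was lost when only the female libraries were fitted (adjusted p = 5.3e-02; range over all settings 1.4e-03 to 6.1e-02). That of AAEL014125 was lost with the split by identical-copy share as a term (adjusted p = 6.7e-02, with 6.1e-05 as the lowest of the settings). Head transcripts stood at 34.1% to 67.8% of the head level in the female pedicels of this comparison. At an adjusted p under 0.01, 2484 genes were called.

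**Figure D5:**
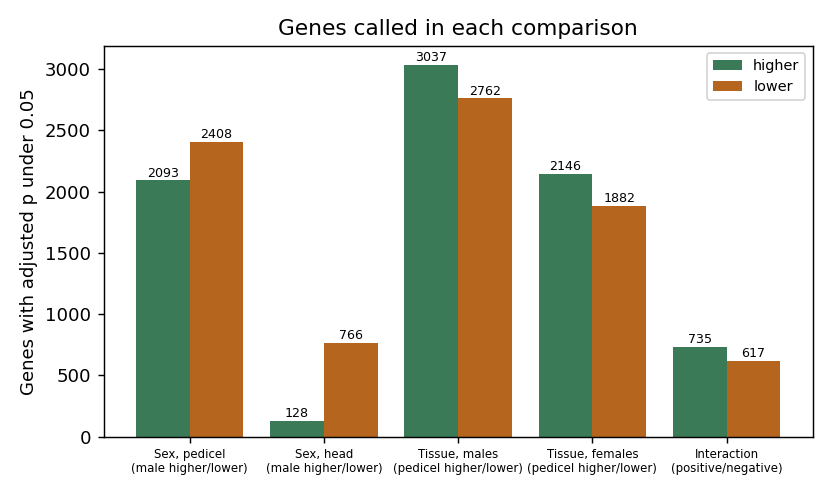
Number of genes called at an adjusted p under 0.05 in each comparison, out of 11381, with genes in the positive direction in green and in the negative direction in brown. Tissue in males gives the most calls (3037 and 2762) and sex in the head the fewest (128 and 766), and in all comparisons but sex in the head the larger of the paired bars changes under at least 1 other scaling or test.

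Tissue differences of males and females overlapped. Called in both sexes were 2963 genes, 1573 higher in the pedicel in both, 1322 higher in the head in both and 68 in opposite directions, where independent lists would share 573, 457 and 1020 (Fisher's exact test over genes, odds ratio 4.43, p = 1.7e-287). Called in males alone were 2836 genes and in females alone 1065, so 73.6% of the calls in females were also calls in males. The log2 folds correlated across genes with a Pearson r of 0.79 and a Spearman rho of 0.72, and genes are not independent replicates.

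Whether the sexes differ more in 1 tissue than in the other was tested as the interaction of sex and tissue. The difference between male and female was not equal in pedicel and head for 1352 genes (11.9%), with 735 positive (male over female larger in the pedicel) and 617 negative, a balance that turned to 720 and 796 with limma-voom and to 792 and 829 with the split by identical-copy share as a term. The 617 became 376 without male pedicel 1 or 5 and 386 without female pedicel 4. At a fold of at least 2, 304 were positive and 415 negative, and at a fold of at least 4 the numbers were 48 and 187. AAEL029085 stood at 39.2 ± 11 CPM in male pedicels, 3.56 ± 1.46 in female pedicels, 1.44 ± 0.349 in male heads and 2.26 ± 2.2 in female heads (SD, n = 5 each; interaction log2 fold 4.09, SE 0.63, edgeR adjusted p = 4.3e-04), and its log2 fold was 3.30 without female head 4. AAEL027785 stood at 25 ± 7.04, 1.66 ± 0.439, 1.1 ± 0.623 and 0.971 ± 0.374 CPM in the same order (log2 fold 3.79, SE 0.48, adjusted p = 6.9e-05). AAEL017043 was highest in female pedicels, at 10.8 ± 2.77 CPM, against 0.319 ± 0.416 in male pedicels, 0.285 ± 0.327 in male heads and 0.167 ± 0.0598 in female heads (log2 fold -6.23, SE 1.12, adjusted p = 1.5e-03; -5.44 without male head 4 and -6.89 without male pedicel 4). For AAEL022711 the male excess was smaller in the pedicel than in the head (log2 fold -6.02, SE 1.36, adjusted p = 8.2e-03), since female pedicels held 3.16 ± 5.35 CPM and female heads 1 count. As a ratio of ratios of counts this was a log2 of -6.82, with a 95% counting interval of -12.12 to -4.34 from that 1 count. Female pedicel 2 held 12.7 CPM of AAEL022711, and without it the log2 was -4.68 (-9.99 to -2.21), with the call kept (adjusted p = 9.3e-04). Without female head 3, which held the count, it was -4.89 with female heads set at the floor of 3 counts over the group.

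A fold of at least 4 over both the other sex and the other tissue, together with a called interaction, was met by 36 genes in male pedicels, AAEL027785 and AAEL029085 among them, 19 genes in female pedicels, AAEL017043 among them, 2 genes in male heads and 0 in female heads. The low number for female heads follows in part from the rule, since 17 genes in all were called at least 4-fold higher in the female head than in the female pedicel, where head transcripts stood at 34.1% to 67.8% of the head level. At a fold of at least 2, the numbers were 195, 49, 10 and 2, and at a fold of at least 8 they were 5, 12, 1 and 0, with female pedicels ahead of male pedicels. These classes were defined after seeing the data. Without male pedicel 2, whose head transcripts stood at 36.6% of the head level, 2694 genes had an interaction, 1104 positive and 1590 negative. The interaction count was 466 with the pedicels at 10% or less of identical-copy transcripts, male pedicel 2 among them, and 2275 with those above 20%, so the split and the presence of male pedicel 2 changed together. It was 426 with library totals alone (299 positive and 127 negative), 497 at an adjusted p under 0.01 (350 positive and 147 negative) and 3229 with voom and sample quality weights (1397 positive and 1832 negative).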

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

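The interaction tests were fixed before the data were examined. The other tests in this part, the counts over other splits of the libraries included, were chosen after the results were seen, as were the fits that leave out libraries in doubt, split the pedicels or use the level of head transcripts.

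Dixon's criterion was run in 39 groups of 5 libraries: the depth, the identical-copy share, the level of head transcripts and the median of the female-limited genes in each group, and each named gene in the groups of its own comparison where its mean was at least 10 CPM, so that other groups of these genes were not tested. In these, 5 values lay far from the other 4 of their group, where chance gives about 1 in 20, or 2. They were the level of head transcripts in male pedicel 2 (36.6%), AAEL009991 in the same library (201 CPM), AAEL019334 in male pedicel 3 (1790 CPM), AAEL020035 in female pedicel 2 (193 CPM), and the median of the 52 female-limited genes in male head 5 (0.0879 CPM, the other 4 male heads being at 0).

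By the interaction test, the difference between male and female libraries was not equal in pedicel and head for 1352 genes. Head transcripts stood at 54.6% of the head level in female and 11.4% in male pedicels. Whether head RNA gave part of these interactions was not tested. Among the named genes the interaction log2 folds were 4.09 for AAEL029085, 3.79 for AAEL027785, -6.23 for AAEL017043, -6.02 for AAEL022711 and -2.52 for AAEL009991.

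The first pattern weighed is that 2408 genes were higher in female and 2093 in male pedicels while head transcripts stood at 54.6% of the head level in female and 11.4% in male pedicels, so that RNA of the head in the pedicel libraries, and its dilution of pedicel RNA, may account for sex calls. Against this for part of the genes, a mixture of male-like pedicel and head RNA lies between its sources. But 611 of the 2408 (25.4%) were called higher in the female pedicel than in the female head. With library totals alone this was 123 of 770 (16%). Of the 2093, 524 (25%) were called lower in the female pedicel than in the female head (40.6% with library totals alone). Of all 11381 genes, 2146 were called higher and 1882 lower in the female pedicel than in the female head. With library totals alone these were 753 and 3243. The sex and tissue comparisons use the same female pedicels, so chance shifts there enter both and can enlarge the 611 and the 524. Also, 76 of the 2093 (3.63%) exceeded by more than 2 standard errors the log2 fold of 1.57 that dilution at the measured levels can give. This cut was not adjusted for the number of genes, which were already chosen as male-higher. The errors come from the fit of all libraries, where heads varied less than pedicels, so the 76 may be too many. For the other parts, head RNA and a sex difference cannot be told apart. The log2 ratios of 87 head transcripts to their mean in heads had a median absolute deviation of 0.48 to 1.25 in female pedicels. It was 0.42 to 0.87 in male pedicels and 0.14 to 0.31 in heads, where a ratio to these same heads keeps it small. Of 1773 genes abundant in the head, 19, 58, 6, 7 and 27 lay under 50% of the library's level of head transcripts in female pedicels 1 to 5, against 0 to 8 in heads. In male pedicels, which were the lowest libraries when the 50 were chosen, 0 to 5 genes did. Each head was set against the mean of these same heads, which keeps its count low. These counts thus cannot decide for any female pedicel whether it held a single share of head RNA at this level. In male pedicel 2, the 961 female-higher genes with a higher mean in female heads than in female pedicels (39.9%, against 44.7% of all tested and 56.6% of male-higher genes) lay higher than in the other male pedicels by a median log2 of 0.77 (0.11 for the 611) and 85.4% of the 2017 male-higher genes within the dilution limit lay lower, but that library was chosen for its head transcripts and 41 of the 50 are among the 961, so its values decide nothing. With the level as a covariate, which correlated with sex at 0.85 and so cannot be separated from it, 142 of the 4501 calls were kept (150 in all), as folds shrank and errors grew (median log2 fold of female-higher genes from -0.96, SE 0.24, to -0.65, SE 0.39, and of male-higher genes from 0.73, SE 0.18, to 0.44, SE 0.31, with the sign kept by 2071 of 2408 and 1882 of 2093), and a sex difference of the pedicel itself stays open for all parts and was not tested.

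The second pattern is the set of 52 female-limited genes, whose median CPM was 42.2 ± 21.7 in female pedicels and 33.7 ± 15.2 in female heads (SD, n = 5 each), and which moved together between libraries, with 50 of 52 above their mean over the female libraries in female head 4 and 3 of 52 in female pedicel 3. A candidate explanation is one other RNA source with a fixed profile in all female libraries. For 5 of the 52 genes the ratio of pedicel to head differed from the median log2 of 0.19 (adjusted p under 0.05, range of the set -1.29 to 6.24), and a single source gives a single ratio, so it is not the sole source of those 5. For the other 47, such a source and female-specific expression in both tissues cannot be told apart: their profile correlated between tissues at a median of 0.90 (highest 0.95) and within a tissue at a median of 0.96 (lowest 0.74), which their choice by a shared ratio partly fixes, and over all 52 the median was 0.76 between tissues against 0.96 within heads and 0.92 within pedicels. Sex-specific expression stays open and was not tested.

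The third pattern is the share of identical-copy transcripts, which was 10% or less in 3 male and 2 female pedicels and above 20% in 2 male and 3 female pedicels, and which could mark a library batch. Sex calls in the pedicel were found on both sides of this split. Within the libraries of low share 3324 genes were called, and within those of high share 4081. Of these, 2878 and 3087 were among the 4501 called in all. Both fits kept all head libraries, which varied less than pedicels, so the counts may be too high. How many sex calls such a batch leaves cannot be read from them. With the split as a term in the fit, 5356 genes were called, and without the copies 4373. The interaction count was 466 and 2275, but male pedicel 2, without which it was 2694, is on the low side, so the split is not shown to be what moved it. What the copies are stays open, and no biological explanation was tested.

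For each comparison, 100 splits of the libraries into groups of the same sizes were drawn, the real one included. For the counts of the sex and tissue comparisons, the share of splits with as many calls was under 0.05. Chance is thus unlikely but not excluded, and the splits treat libraries as independent, which the labels do not state. For sex in the pedicel, 1 of 100 splits gave as many calls (4501; highest other 4034, with male pedicel 2 and female pedicel 3 exchanged). Tissue in males gave 1 of 100 (5799; highest other 2944, with male pedicel 2 and male head 2 exchanged), and tissue in females 1 of 100 (4028; highest other 10). For sex in the head, 2 of 100 gave as many (894; highest other 1323, with male head 2 and female head 3 exchanged), which points to a structure of the head libraries besides sex. In 54 female-limited genes chosen by the same rule without these libraries, the median was 0 CPM in male head 2 and 16 CPM in female head 3, each on the side of its label. For the interaction, 2 of 100 gave as many (1352; highest other 1792), the other being a split that kept the sexes apart in the pedicels and mixed them in the heads, but such splits remove the sex effects themselves and so do not test whether these are equal in the tissues.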

How the results depend on the processing

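Of the values for named genes under other settings, 462 under planned and 95 under added settings kept their direction and their side of the threshold, none reversed, and 7 and 4 lost the call with the direction kept, in AAEL028731, AAEL019334, AAEL011275, AAEL020035, AAEL024800 and AAEL014125. DESeq2 gave no adjusted p for 3 values. Leaving out 1 library moved the fold by over 1.5 times in 17 of 240 values. Unless said otherwise, the cause of the changes below was not tested. The settings without libraries in doubt, by identical-copy share and with the covariate were chosen after seeing the data.

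Counts of calls stayed within 1.5 times of those reported with RLE factors, with TMM without the 20 most abundant genes and without a filter. They did so too at a mean of 1 CPM, with DESeq2, with limma-voom and without identical copies. With library totals alone, sex in the head fell to 571 and the interaction to 426, the median log2 fold of all genes moved to 0.35 (sex, pedicel), 0.10 (sex, head), -0.12 (tissue, males), -0.43 (tissue, females) and 0.29 (interaction), and the share of higher calls went from 46.5% to 77.3%, 14.3% to 31.2%, 52.4% to 38.3%, 53.3% to 18.8% and 54.4% to 70.2%. Fits of only the groups compared gave 3269 for sex in the pedicel and 1551 for sex in the head, where a separate spread for each tissue applies, and voom with sample quality weights gave 3229 for the interaction. An adjusted p under 0.01 left 520 (sex, head), 2484 (tissue, females) and 497 (interaction), and an absolute log2 fold of at least 1 left 1743, 521, 3037, 1485 and 719 in the order above, with 344 genes shared in direction between the sex comparisons (648 without this limit) and 1218 between the tissue comparisons (2895), fewer by construction. Without male pedicel 2 the interaction rose to 2694, and without male head 2 and female head 3 sex in the head rose to 1661. The interaction was 466 in pedicels of low and 2275 in those of high identical-copy share, with fewer libraries each and male pedicel 2 in the first alone, and sex in the pedicel was 150 with the covariate, which correlated with sex at 0.85.

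Leaving out each library in turn gave 3753 to 5358 calls for sex in the pedicel, 649 to 1198 for sex in the head, 5307 to 6128 for tissue in males, 3240 to 4102 for tissue in females and 911 to 2694 for the interaction, the last without male pedicel 2, the only library to move a total by over 1.5 times. Counts by direction moved more: male-higher head calls (128) ran from 81 to 334 and negative interactions (617) from 376 to 1590. Same-direction overlaps ran from 496 to 753 and from 2405 to 2886. Replicate numbers were not taken as pairs, since in no pair of groups did all 5 same-number deviations correlate above 0.1 (2 to 4 of 5 did; range -0.09 to 0.41) and at most 3 of 5 libraries correlated best with their own number. Other numbers correlated at a mean of -0.06 to -0.01, and pedicels 1 and 2 of both sexes had low and 3 and 4 high identical-copy shares, so a number may mark something shared. With the replicate block (the replicate number as a term), 5048, 1208, 6254, 4565 and 1990 genes were called, in the order above, and no total moved by over 1.5 times, but male-higher head calls went from 128 to 304 (260 with DESeq2) and the interaction's from 735 positive and 617 negative to 993 and 997. Gene lists and chromosomal location were not run, since no ID matched a name or position. Depth limits genes near 0, whose folds are bounds, ratios of few counts or fitted values that rest on few counts.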

Other observations

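The tests of isoform usage and the choice of examples in this part were made after the data were seen.

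Sexes and tissues also differed in which transcripts of a gene were used. Among 3387 genes with at least 2 tested transcripts, transcript usage differed between males and females in 104 genes in the pedicel and in 41 in the head (edgeR, Simes' method, adjusted p under 0.05), and between pedicel and head in 291 genes in males and 109 in females. At an unadjusted p under 0.05 the numbers were 394, 216, 627 and 452, and with only the groups compared the called genes numbered 93, 78, 339 and 145. The sex comparisons shared 7 genes, where independent lists would share 1.26, and all 7 transcripts called in both moved in the same direction. For these tests the estimated counts of each transcript were rounded to whole numbers. After rounding, AAEL017331-RB had no counts in any female library. It stood at 1.95 ± 1.52 CPM in male pedicels and 3.36 ± 1.71 CPM in male heads (SD, n = 5 each; edgeR adjusted p = 4.6e-03 and 4.8e-04). AAEL012513-RP had no counts after rounding in any male library. It stood at 6.28 ± 4.18 CPM in female pedicels and 11.7 ± 2.98 CPM in female heads (adjusted p = 1.0e-04 and 1.8e-04). How reads were divided between transcripts of 1 gene is not given in the sources used here, so single transcripts are less certain than genes.

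Some abundant genes differed widely between pedicel libraries of 1 group. AAEL028790 stood at 5230 and 12700 CPM in male pedicels 3 and 4, which had the highest shares of identical-copy transcripts among male pedicels (21.9% and 35.2%), and at 41.4 to 363 CPM in the other 3. AAEL028731 stood at 22100 and 17000 CPM in female pedicels 3 and 5 and at 46.6 to 2590 CPM in the other 3. The 20 most abundant genes took 29.4% to 71.7% of the counts of a pedicel library and 33.6% to 40.2% of those of a head library.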
